A study of Mus musculus with 4 samples.

How the data were processed

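Single-cell RNA-seq was measured in hematopoietic stem cells (HSCs, the cells that renew the blood system) taken from the bone marrow of 4 recipient mice at 4 months after transplantation. Per the labels, the donor cells carried genetic barcodes and a green fluorescent reporter, were isolated by cell sorting, and were made into droplet libraries with a 3' chemistry, 1 library per mouse. The labels give 1 group and no treatment, so all 4 mice form 1 group, and the mouse numbers 1 to 4 only name the libraries. The clonal barcodes were not used here.

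The deposited values are counts of unique molecular identifiers (UMIs, tags that mark single RNA molecules) per gene and cell barcode, whole numbers that were not normalized. Per the submitters' processing notes, the tools named are bcl2fastq and Cell Ranger 2.1.0 and the genome build is mm10. The deposited matrices hold 27998 genes and 7604 barcodes (1861, 1262, 2842 and 1639 for mice 1 to 4), with 74983237 UMIs in all. Of the gene identifiers, 27722 (99.0%) were found in GENCODE M21 on GRCm38, which gave the positions printed. How reads shared by near-identical genes were assigned is not given in the sources used here, so paralogs such as Hba-a1 and Hba-a2, the Hbb genes, and S100a8 or H2 family members with close copies may share counts.

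Cells were kept with at least 500 genes and at most 10% of UMIs from the 13 mitochondrial genes. Scrublet, run per mouse through scanpy, then called 22 doublets among 7315 cells (0.301%). At that rate the caller did not work on these data, so doublets must be taken as still present among the 7293 kept cells. Mice 1 to 4 kept 1665, 1235, 2804 and 1589 cells, with medians of 7559, 9247, 8600 and 8628 UMIs and of 2212, 2569, 2412.5 and 2419 genes per cell. For shares of cells and for classes of cells, each cell was thinned without replacement to 5000 UMIs, the largest multiple of 500 that kept at least 80% of cells in every mouse. This left out 303, 21, 226 and 132 shallower cells (682 in all) and used 6611. Among those cells a count of 0 allows, as 3 counts of the total, a share of up to 0.220%, 0.247%, 0.116% and 0.206% in mice 1 to 4. Shares in 1 mouse have exact 95% binomial intervals, which cover counting error only.

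For clusters, log-normalized values of the 2000 genes of highest variance within mice were centred within each mouse. Leiden clustering at resolution 0.6 followed, on 30 principal components and 15 nearest neighbours. A cluster was called after a cell type where at least 3 of that type's markers were among its 50 leading genes by fold over all other cells, taking the list with the largest share of its members there. Names came only from the erythroid, erythroblast, myeloid progenitor, lymphoid progenitor and mature, endothelial or stromal lists. The HSC, strict mitotic, platelet and megakaryocyte, megakaryocyte and multipotent progenitor lists gave no name. So clusters 1 and 7 stayed unnamed with 4 and 3 platelet and megakaryocyte markers, clusters 2 and 3 with 4 and 3 multipotent progenitor markers, clusters 6 and 7 with 16 and 7 strict mitotic markers, cluster 1 with 3 megakaryocyte markers, and clusters 0 and 4 with 6 and 3 HSC markers. An HSC compartment was also defined, as clusters with no name by this rule and with summed HSC-list CPM (a gene's UMIs scaled to a common library total) of at least 25% of the highest cluster. It is a set of clusters and not a cell type, and of its 8 clusters only cluster 0, with 2, had HSC-list genes among the 10 leading genes. There cluster 1 had 2 megakaryocyte markers, clusters 2 and 3 had 2 multipotent progenitor markers each, and clusters 6 and 7 had 6 and 3 strict mitotic markers. The rule for cluster names and this definition were made after the data had been seen, and Ly6a was left out of its sum after a cluster led by Jchain was seen to pass through Ly6a alone. That cluster, left unnamed, held 2.94%, 0.243%, 1.14% and 1.70% of mice 1 to 4. The compartment held 6526 cells, or 91.0%, 76.0%, 93.4% and 91.4% of mice 1 to 4.

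The comparisons were made within mice, between classes of cells, with the mouse as replicate. Cells in the top 10% by the number of S and G2/M phase genes detected were set against the bottom 50%. Cells with at least 1 UMI of Vwf were set against cells with 0. Cells in the top 25% by the number of HSC-list genes, and likewise of immediate-early genes, were set against the bottom 50%. The classes are ranges of a score and not types. Except for Vwf they were ranked within each mouse, so a score high in 1 mouse can be low in another. The HSC-list high class began at 6 genes in mouse 2, and the low class reached 7 in mouse 4. The immediate-early high class began at 4 genes in mouse 3, and the low class reached 4 in mouse 1. The lowest score of a high class was shared by 4 to 24 cells per mouse for the cycle classes, 151 to 387 for the HSC-list classes and 148 to 446 for the immediate-early classes, with ties broken at random. Unthinned UMIs of each class were summed per mouse, giving 8 sums per comparison, and the genes that made the classes were left out.

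The sums were tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). The mouse was a block, since both classes came from the same animals, and the pairing comes from that design. Gene lists with at least 3 tested genes were tested with camera in limma at a preset correlation of 0.01, beside an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists. Counts of list members are given over all genes tested, and also adjusted over the list alone. Cell type lists covered HSC, strict mitotic, platelet and megakaryocyte, megakaryocyte, erythroid, erythroblast, myeloid progenitor, lymphoid progenitor, multipotent progenitor, B cell, T or NK cell, neutrophil, monocyte or macrophage, dendritic, mast cell or basophil, endothelial and stromal genes. Process lists covered S phase, G2/M phase, immediate-early, heat shock, interferon, MHC class II, MHC class I, glycolysis, oxidative phosphorylation, quiescence, growth and biogenesis, ribosomal protein, X inactivation and Y-linked genes. The lists overlap, for instance all 20 strict mitotic genes against G2/M genes, and erythroblast against erythroid genes. The ribosomal list was taken by name (Rpl or Rps and a digit), so it also takes in other genes so named, such as Rps6ka6, a kinase gene, and Rps27l. Its counts are of genes so named and not of ribosomal proteins alone.

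Genes were named by a rule. For each comparison these were the 12 largest positive and 12 largest negative log2 fold changes among genes past the threshold, with 1 direction in all 4 mice and a mean of at least 50 CPM. Predicted, ribosomal and mitochondrial genes were left out of that ranking, and up to 4 members of each list called were added. Levels were named for HSC-list genes and the most abundant gene of each other cell type list. Spread was named for the 12 genes of largest standard deviation (SD) of log2 CPM over mice. The text names part of these. The same rule was applied again within the HSC compartment. Vwf was named as the index of its comparison, and Gkn3 levels were added after its values were seen. The grouping, the tests, the lists, the rule for named genes and most of the alternatives were fixed before the data were examined.

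Mitotic cells were those with at least 3 of 20 strict mitotic genes at the thinned depth. Spread between mice was edgeR's common biological coefficient of variation over the 4 sums of all kept cells. Each pair of libraries differed beyond sampling noise (chi-square per degree of freedom 10.3 to 72.6), and pairs shared only 1 to 8 barcodes, so each library was counted as its own sample. On simulated counts with known changes the edgeR step recovered 81%, 100%, 57% and 69% of 1.5-fold changes and 100%, 100%, 98% and 98% of 2-fold changes in the cycle, Vwf, HSC-list and immediate-early comparisons. Those steps ran on 10535, 11337, 10973 and 11035 genes, and 6.70%, 6.10%, 7.74% and 7.22% of their calls were false. Alternatives were DESeq2 size factors, a DESeq2 test, no filter, no replicate block, each mouse left out, thinned counts, doublets kept, at most 5% mitochondrial UMIs, another seed, other class limits, and cells without mature-lineage clusters or mitotic cells. The mature-lineage clusters were the B cell-like, neutrophil-like, erythroblast-like and T or NK cell-like ones. The erythroid-like, myeloid progenitor-like and Jchain-led clusters stayed in, apart from mitotic cells where those were removed. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1 and scikit-learn 1.9.0. The immunoglobulin and T cell receptor constant genes Ighm, Igkc and Trac were not analysed here, and single values of some list genes are not reported here.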

Results

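Sorted HSCs of 4 transplanted mice were profiled by droplet single-cell RNA-seq, with 1 library per mouse. The libraries of mice 1 to 4 held 14687097, 17168125, 27878190 and 15249825 UMIs. With 1 group of mice and no treatment, the design allows a description of the sorted cells and comparisons between classes of cells within the same animals. Values are means ± SD over n = 4 mice unless stated, and log2 fold changes carry approximate standard errors (SE). Each SE is the size of the fold change divided by the square root of the quasi-likelihood F statistic. It was not estimated directly, and may be too small for genes almost absent from a class.

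The 19 HSC-list genes ranged from 5.33 to 276 CPM. Mecom, a transcription factor needed by HSCs (chromosome 3, 29951296 to 30548008, minus strand, GRCm38), stood at 183 ± 69.5 CPM, and Procr, a surface receptor used to isolate HSCs (chromosome 2, 155751117 to 155755471, plus strand), at 102 ± 41.6 CPM. Hlf was at 142 ± 53.3 CPM, Mllt3 at 177 ± 60.7, Meis1 at 242.5 ± 62.3, Angpt1 at 174 ± 46.8, Ly6a at 276 ± 106, Esam at 55.0 ± 16.99 and Hoxb5 at 15.9 ± 5.13. The lowest were Ctnnal1 at 10.8 ± 3.07 CPM, Tek at 8.04 ± 2.0003, Fgd5 at 7.93 ± 3.65, Robo4 at 7.64 ± 2.81 and Tcf15 at 5.33 ± 2.69. Summed over the 19 HSC-list genes, mice 1, 3 and 4 stood at 2073, 1936 and 1986 CPM and mouse 2 at 869.5, with a mean of 1716 ± 567. In the HSC compartment the sums were 2239, 1582, 2109 and 2106 CPM in mice 1 to 4. At the thinned depth Procr was detected in 39.3% ± 10.2 of cells. It was detected in 2 of 405 erythroid-like cells (0.494%), whose median was 27609 UMIs before thinning against 8581 in the HSC compartment.

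Genes of other lineages were also measured. S100a8, a neutrophil gene, stood at 1441 ± 708 CPM over all kept cells and at 30.7 ± 7.90 CPM in the HSC compartment, and Hbb-bs, a beta globin gene, at 2095.0 ± 366 and 78.5 ± 25.4. Lyz2, a myeloid lysozyme gene, was at 435 ± 157 CPM over all kept cells and 323 ± 14.4 in the HSC compartment. Over all kept cells Cd52 was at 89.5 ± 43.1, Cd79b at 37.8 ± 15.7, Nkg7 at 76.8 ± 32.7 and Cdk6 at 128 ± 66.4. The most abundant dendritic, mast cell, endothelial and stromal genes were Irf8 at 9.66 ± 3.73 CPM, Cpa3 at 5.89 ± 3.19, Cldn5 at 2.29 ± 2.18 and Lepr at 3.86 ± 2.48. Xist, the RNA that silences an X chromosome, was at 1969.9 ± 129 CPM, while the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0, 0, 1 and 4 UMIs over all kept cells.

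The cells fell into 15 clusters. Cluster 0, led by Ifitm1, Sult1a1, Ltb and Procr, held 52.7%, 41.0% and 54.3% of mice 1, 3 and 4 but 1.30% of mouse 2. Cluster 3, led by Cd34, H2-Aa and Sox4, held 49.9% of mouse 2 (95% interval 47.1 to 52.7), 0.0713% of mouse 3 and no cell of mice 1 and 4, which allows shares of up to 0.180% and 0.189% as 3 counts of the kept cells, with exact upper bounds of 0.221% and 0.232%. These shares rested on the centring within mice. Without it, the best match of cluster 0 (0.495 of the cells in either cluster were in both) held 37.0%, 15.95%, 26.5% and 31.7% of mice 1 to 4. The best match of cluster 3 (0.153 in both), which was also that of cluster 2, held 13.8%, 15.2%, 8.45% and 8.06%. Cluster 1, led by replication genes, held 17.2%, 14.1%, 16.4% and 16.6% of mice 1 to 4, and without centring its best match held 14.6%, 22.3%, 15.5% and 15.4%. At resolutions 0.3 and 1 its best match held 26.9% and 0.405% of mouse 2. Cluster 4, led by Gkn3, a gastrokine family gene (chromosome 6, 87383256 to 87388935, minus strand), held 15.1% of mouse 3 (13.8 to 16.5) and 2.76%, 0% and 1.38% of mice 1, 2 and 4, and Gkn3 itself stood at 24.7, 0.950, 122 and 5.24 CPM in mice 1 to 4.

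Cells of other lineages were present in the sort. Erythroid-like cells, led by Car1, Klf1 and Ermap, held 21.6% of mouse 2 (19.4 to 24.0) against 1.98%, 3.03% and 1.51% of mice 1, 3 and 4, a mean of 7.04% ± 9.74 that was 2.15% without mouse 2. Without centring their best match held 21.6% of mouse 2 as well. Their median of 27311 UMIs was above that of every other cluster. They were not rich in globin, as Hbb-bs was detected at the thinned depth in 22.5% of them, against 30.3% ± 8.49 of HSC-compartment cells. Smaller clusters were B cell-like (64 cells), neutrophil-like (57), erythroblast-like (51), myeloid progenitor-like (42) and T or NK cell-like (33), and 1 unnamed cluster of 111 cells was led by Jchain, Mzb1 and Slpi. A cluster of 20 cells was led by interferon genes. With 1 library per mouse these differences between mice have no replicate check.

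**Figure D1:**
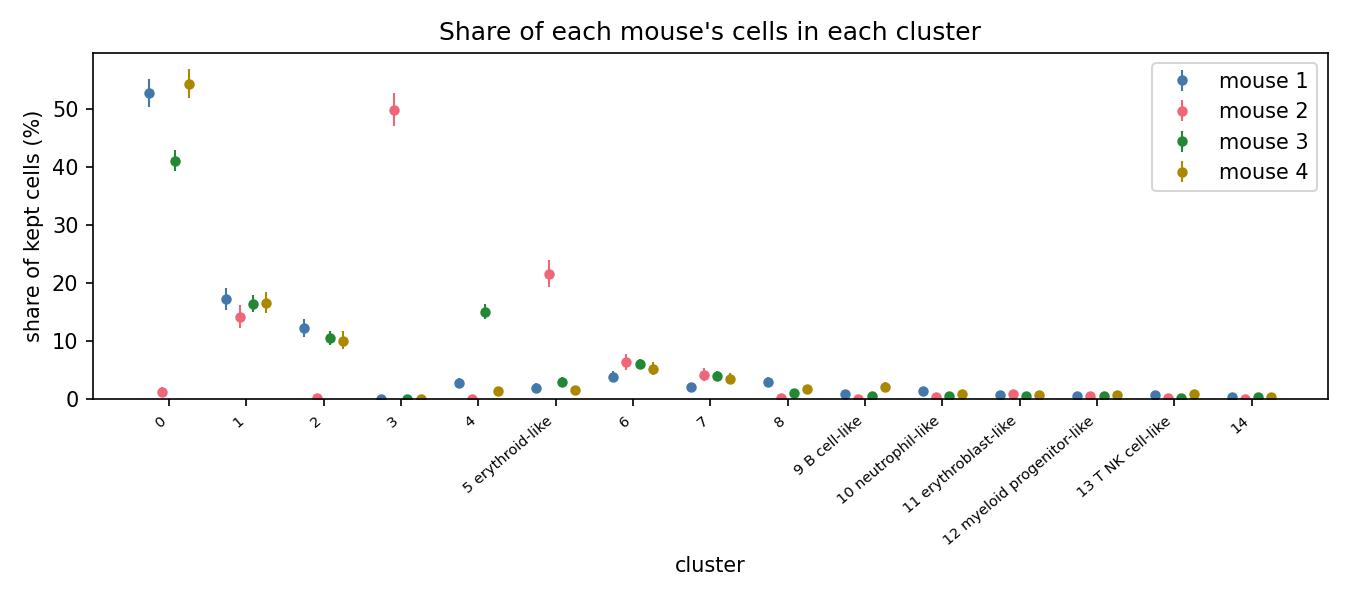
Share of each mouse's kept cells (y axis, %) in each of the 15 clusters (x axis), with 1 point per mouse and bars for exact 95% binomial intervals. Mouse 2 stands apart in cluster 3 (49.9%) and in the erythroid-like cluster 5 (21.6%), and mouse 3 in cluster 4 (15.1%), but without centring within mice the best match of cluster 3 held 15.2% of mouse 2 and 13.8% of mouse 1.

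Mitotic cells made up 17.3% ± 10.6 of cells. The shares were 10.4% of mouse 1 (95% interval 8.78 to 12.1), 32.9% of mouse 2 (30.3 to 35.7), 14.7% of mouse 3 (13.3 to 16.1) and 11.3% of mouse 4 (9.74 to 13.1). In the HSC compartment they were 8.46%, 18.3%, 12.5% and 10.0%, with a mean of 12.3% ± 4.32. Without thinning the mean over all cells was 21.3%.

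Gene levels differed between mice. The largest SDs of log2 CPM were those of Mt2 (1.93), a metallothionein, and Car1 (1.86), an erythroid carbonic anhydrase at 155, 1349, 199.7 and 61.5 CPM in mice 1 to 4. They were followed by Mzb1 (1.76), Myl10 (1.73), Slpi (1.64) and Jchain (1.62), which joins immunoglobulin chains and stood at 3810.3, 294, 1635 and 2511 CPM. The coefficient of variation between mice was 22.4% over 11539 genes, 11.5% in the HSC compartment and 10.1% without mouse 2. In the compartment the largest SDs were those of Myl10 (1.45), Slfn2 (1.02) and Pf4 (0.87), a platelet chemokine at 209, 793, 644 and 349 CPM. Pearson's r of log2 CPM across genes was 0.957 to 0.967 for pairs with mouse 2 and 0.991 to 0.993 for the other pairs, and genes are not independent replicates.

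Cells detecting many cell cycle genes were low in HSC, MHC class II, interferon and immediate-early genes. These 4 lists passed camera's threshold at the preset correlation, with adjusted p = 0.276 to 0.412 with an estimated correlation. Of 10654 genes tested, 2895 were higher and 3052 lower in these cells than in the cells detecting fewest. Within the HSC compartment 2929 were higher and 3175 lower of 10277. Higher genes included Pbk (7.03 ± 0.26 on the log2 scale), a mitotic kinase, Ccna2 (6.93 ± 0.19), cyclin A2, and Tk1 (6.21 ± 0.20), a thymidine kinase. Lower ones included Jchain (-6.67 ± 0.70), Ltb (-3.60 ± 0.16), a lymphotoxin, Cd74 (-3.56 ± 0.21), the MHC class II invariant chain, and Procr (-3.44 ± 0.19), each in 4 of 4 mice. Jchain went the other way in the compartment, at 1.21.

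Of 19 HSC genes, 17 were lower and 0 higher in cycling cells (median -1.20, and 17 lower adjusted over the list alone). Ly6a (-2.95 ± 0.15), Mllt3 (-1.90 ± 0.10) and Pdzk1ip1 (-1.57 ± 0.09) were among them. All 7 MHC class II genes were lower (median -1.80, and 7 adjusted over the list alone), as were 5 of 7 MHC class I genes (median -0.64, 5 adjusted over the list alone) such as B2m (-0.69 ± 0.06). Of 21 interferon genes 19 were lower (median -0.99, 19 adjusted over the list alone), with Ifit1 at -3.40 ± 0.20. Of 17 immediate-early genes 14 were lower (median -1.56, 15 adjusted over the list alone), with Junb at -2.27 ± 0.12 and Dusp1 at -1.97 ± 0.11. Of 10 quiescence genes 7 were lower (median -0.85, 7 adjusted over the list alone), with Txnip at -2.11 ± 0.11 and Foxo1 at -1.60 ± 0.18. Of 99 ribosomal protein genes 60 were lower and 6 higher (median -0.21, 60 and 7 adjusted over the list alone). These lists had camera adjusted p from 1.4e-07 to 0.0172, and adjusted p = 0.276 to 0.602 with an estimated correlation.

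In the other direction, 22 of 24 oxidative phosphorylation genes were higher in cycling cells (median 0.80, 22 adjusted over the list alone), among them Cycs (1.85 ± 0.12), cytochrome c. Of 20 growth and biogenesis genes 17 were higher (median 0.96, 17 adjusted over the list alone), with Ranbp1 at 1.60 ± 0.07, and of 8 heat shock genes 7 were (median 0.71, 7 adjusted over the list alone), with Hsp90aa1 at 1.55 ± 0.14. Erythroid genes were higher for 12 of 17 (median 2.21, 12 adjusted over the list alone), with Klf1 at 4.61 ± 0.18, erythroblast genes for 4 of 9 (median 0.29, 4 adjusted over the list alone) and megakaryocyte genes for 5 of 6 (median 1.47, 5 adjusted over the list alone), with Itga2b, the platelet integrin alpha IIb, at 1.88 ± 0.24. Camera adjusted p for these 6 lists ran from 1.3e-09 to 0.0472, and adjusted p = 0.412 to 0.602 with an estimated correlation. Erythroid-like cells made up 16.2%, 40.5%, 12.1% and 5.52% of the cycling class in mice 1 to 4 and at most 2.97% of the other class, and the cycling class had median depths of 15349 to 17029 UMIs against 7079 to 8055.5.

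Within the HSC compartment, megakaryocyte genes were higher in cycling cells for 6 of 7 (median 2.11, 7 adjusted over the list alone), with Pf4 at 2.98 ± 0.13 and Itga2b at 2.51 ± 0.09, and platelet and megakaryocyte genes for 15 of 21 (median 0.65, 16 adjusted over the list alone). Adjusted p was 0.106 and 0.204 with an estimated correlation. HSC genes were lower there for 16 of 19 (median -0.80, 16 adjusted over the list alone, camera adjusted p = 1.3e-08, adjusted p = 0.0502 with an estimated correlation). In the compartment the cycling class had median depths of 14228 to 16666.5 UMIs against 6846 to 8057. Fold changes compare shares of UMIs, so a gene with unchanged molecules per cell would be lower in the deeper class. Molecules per cell were not compared. The immediate-early, interferon, MHC class I and II, heat shock, oxidative phosphorylation, growth and ribosomal protein lists were called there too, in the directions seen over all cells, with adjusted p = 0.0502 to 0.235 with an estimated correlation. Myeloid progenitor genes were lower there for 3 of 4 (median -0.83, 3 adjusted over the list alone, adjusted p = 0.185 with an estimated correlation). Quiescence genes did not pass there (median -0.53, camera adjusted p = 0.0702). Erythroid genes did not pass there (median 0.51, camera adjusted p = 0.0616), and Car1 was at -0.10. Not called over all cells were the platelet and megakaryocyte (median 0.38, adjusted p = 0.117), myeloid progenitor (0.41, 0.670), lymphoid progenitor (-0.98, 0.0521), multipotent progenitor (-0.45, 0.679), B cell (-1.20, 0.239), neutrophil (-0.51, 0.823), monocyte (0.37, 0.763) and glycolysis (-0.07, 0.754) lists. For glycolysis the test's direction was up, against its median and mean. In the compartment the medians and means of multipotent progenitor (-0.31 and 0.34) and erythroblast genes (-0.38 and 0.09) differed in sign, and neither list was called.

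Cells with a Vwf UMI were higher in platelet and megakaryocyte genes. Both lists of such genes passed camera's threshold at the preset correlation, with adjusted p = 0.125 and 0.120 with an estimated correlation. Vwf, the von Willebrand factor that marks platelet-biased HSCs (chromosome 6, 125546774 to 125686679, plus strand), stood at 35.3, 14.97, 51.5 and 37.6 CPM in mice 1 to 4, and was detected at the thinned depth in 13.7% ± 4.28 of cells and in 2.22% of erythroid-like cells. Against cells without it, 298 genes were higher and 277 lower of 11444 tested. Which side was larger depended on the setting, with 250 higher and 300 lower with DESeq2 size factors, 309 and 551 with no filter, 119 and 160 with a DESeq2 test, 140 and 196 with thinned counts, 234 and 308 with at most 5% mitochondrial UMIs, and 101 and 154 with at least 2 UMIs of Vwf. The mouse block mattered here, with 3 higher and 26 lower without it, and of the 5 higher genes named next only Sdpr passed without it. Mouse 3 weighed most, with 95 higher and 142 lower without it. Higher genes included Gkn3 (1.85 ± 0.18), Pf4 (1.77 ± 0.21), Sdpr (1.62 ± 0.15), Itga2b (1.18 ± 0.14) and Rap1b (0.96 ± 0.12), a platelet GTPase, each in 4 of 4 mice. With Gkn3 at 0.950 CPM over all kept cells of mouse 2, its direction in that mouse rests on few UMIs. The Gkn3 cluster made up 6.38%, 0%, 30.7% and 2.39% of the cells with Vwf in mice 1 to 4 and 1.45%, 0%, 11.9% and 1.12% of those without it.

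Of 20 platelet and megakaryocyte genes 16 were higher in Vwf-detected cells (median 0.83, 17 adjusted over the list alone), and of 7 megakaryocyte genes 5 (median 1.18, 6 adjusted over the list alone). Of 19 HSC genes 8 were higher and 1 lower (median 0.35, 15 and 1 adjusted over the list alone), with Slamf1 at 0.70 ± 0.10 and Hoxb5 at 0.73 ± 0.11. Of 53 G2/M genes 9 were higher (median 0.29, 20 adjusted over the list alone), of 20 strict mitotic genes 2 (median 0.30, 12 adjusted over the list alone) and of 43 S phase genes 4 (median 0.12, 4 adjusted over the list alone). MHC class I genes (median 0.10, 1 of 7 higher, 4 adjusted over the list alone) and ribosomal protein genes (median 0.03, 1 of 101 higher, 0 adjusted over the list alone) were also called up. For these 8 lists adjusted p was 0.120 to 0.30 with an estimated correlation.

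Genes of other lineages were lower in Vwf-detected cells. All 8 neutrophil genes were lower (median -5.63, 8 adjusted over the list alone), with Camp at -6.32 ± 0.11 and S100a8 at -5.77 ± 0.10, as were all 9 erythroblast genes (median -2.69, 9 adjusted over the list alone) and 14 of 17 erythroid genes (median -2.13, 15 adjusted over the list alone), with Car1 at -2.83 ± 0.22. These 3 lists were also called with an estimated correlation, each with adjusted p = 0.0386. Within the HSC compartment S100a8 (-0.15) and Car1 (-0.28) did not pass. Camera called further lists lower at the preset correlation, with adjusted p = 0.0579 to 0.325 with an estimated correlation. These were myeloid progenitor (7 of 11, median -2.11), lymphoid progenitor (2 of 6, -0.97), multipotent progenitor (5 of 8, -0.94), B cell (3 of 4, -2.61), monocyte (2 of 3, -0.73), heat shock (0 of 10, -0.09), MHC class II (1 of 7, -0.07) and growth and biogenesis (1 lower and 1 higher of 20, -0.03). Adjusted over the list alone they had 8, 3, 7, 4, 2, 0, 2 and 4 genes lower. Heat shock and growth genes had medians near 0 and few or no members past the threshold. Within the compartment both of these lists were called higher, the opposite direction. Erythroid-like cells made up 2.73%, 23.3%, 3.81% and 1.92% of the cells without Vwf in mice 1 to 4. They made up 0.532%, 7.07%, 0.209% and 0% of those with it. Not called were immediate-early (median 0.08, adjusted p = 0.806), interferon (0.07, 0.191), glycolysis (0.06, 0.212), oxidative phosphorylation (0.01, 0.549) and quiescence (0.11, 0.103) genes. The test's direction was down for immediate-early genes, against their median and mean, and the mean for oxidative phosphorylation was -0.02.

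**Figure D2:**
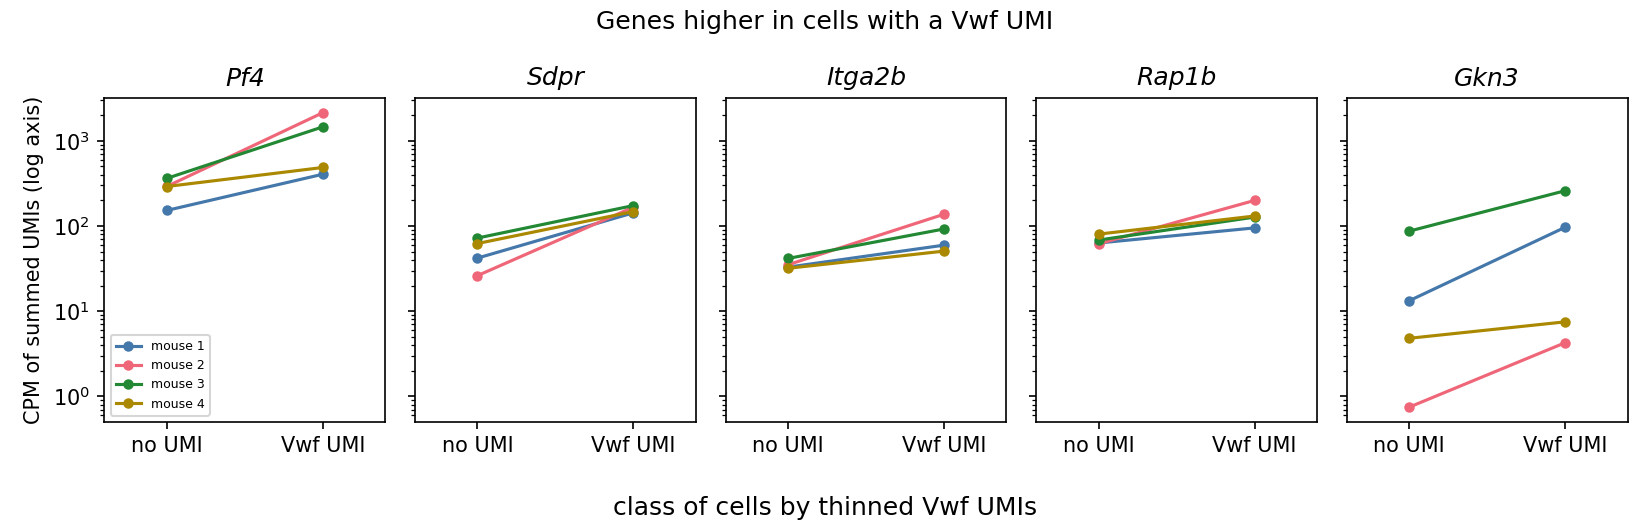
CPM of summed UMIs (log y axis) of 5 genes in cells without and with a Vwf UMI, over all kept cells, with 1 line per mouse and colours for mice 1 to 4. Each line rises in each panel, and Gkn3 runs from below 1 CPM in mouse 2, where its line rests on few UMIs, to its highest values in mouse 3.

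Within the HSC compartment 506 genes were higher and 314 lower of 11101 in Vwf-detected cells, and 326 were called without mouse 3. Gkn3 (1.59 ± 0.13), Pf4 (1.5 ± 0.11), Sdpr (1.32 ± 0.08) and Itga2b (0.92 ± 0.08) were higher, as were Ube2c (1.07 ± 0.08), Birc5 (0.81 ± 0.07) and Mki67 (0.77 ± 0.08), genes of mitosis. Cd34, a surface protein of progenitors (-1.08 ± 0.09), Sox4 (-0.78 ± 0.07), Nkg7 (-0.70 ± 0.09) and Ctla2a (-0.52 ± 0.04) were lower, each in 4 of 4 mice. The Gkn3 cluster made up 6.42%, 0%, 30.9% and 2.42% of Vwf-detected and 1.60%, 0%, 12.9% and 1.21% of other compartment cells in mice 1 to 4. Of 53 G2/M genes 42 were higher (median 0.61, 45 adjusted over the list alone), of 20 strict mitotic genes 19 (median 0.72, 19 adjusted over the list alone), of 43 S phase genes 19 (median 0.21, 25 adjusted over the list alone), and of 20 platelet and megakaryocyte genes 15 (median 0.63, 16 adjusted over the list alone). Of 8 multipotent progenitor genes 6 were lower (median -1.09, 8 adjusted over the list alone), with Cd27 at -0.44 ± 0.06 and Cd48 at -1.90 ± 0.33. Adjusted p for these 5 lists was 0.0859 to 0.152 with an estimated correlation. Mitotic cells made up 8.02%, 25%, 19.6% and 13.0% of Vwf-detected and 8.54%, 17.6%, 10.7% and 9.49% of other compartment cells in mice 1 to 4, and without mitotic cells 302 genes were called. Ube2c (0.17 ± 0.43), Birc5 (0.70 ± 0.32) and Mki67 (0.30 ± 0.30) did not pass there, where cells had been removed by detection of these genes.

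Further lists were called in Vwf-detected compartment cells. Higher were 5 of 7 megakaryocyte (median 0.92), 10 of 24 oxidative phosphorylation (0.12), 5 of 20 growth and biogenesis (0.07) and 2 of 9 heat shock genes (0.12). Lower were 5 of 7 MHC class II (median -0.23), 2 of 5 lymphoid progenitor (-0.69), 3 of 6 erythroblast (-0.25) and 4 of 17 immediate-early genes (-0.03). Adjusted over the list alone the counts were 5, 21, 6 and 3 higher and 5, 3, 3 and 4 lower, and adjusted p was 0.0859 to 0.311 with an estimated correlation. The HSC (median 0.10, adjusted p = 0.213), erythroid (0.12, 0.213), myeloid progenitor (-0.08, 0.287), neutrophil (-0.15, 0.210), interferon (-0.03, 0.210), MHC class I (-0.01, 0.688), glycolysis (-0.02, 0.688), quiescence (-0.02, 0.688) and ribosomal protein (-0.0026, 0.303) lists were not called. The means of the glycolysis (0.01) and quiescence (0.03) lists were above 0, against their medians.

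Cells detecting many HSC genes were high in lymphotoxin, interferon-related and antigen presentation genes and low in replication genes. The interferon, MHC class I, MHC class II and S phase lists had adjusted p = 0.161 to 0.416 with an estimated correlation over all cells, and in the compartment S phase passed (adjusted p = 0.0473) and the others did not (adjusted p = 0.221). Over all cells 1523 genes were higher and 2173 lower of 11115. Leaving out mouse 1, 3 or 4 gave 525 higher and 1258 lower, 236 and 866, or 682 and 1442, and no mouse block 903 and 1814. Over all cells the low class included 44.0% erythroid-like cells in mouse 2 and 4.85%, 6.28% and 3.30% in mice 1, 3 and 4, and the high class none. Within the HSC compartment 2304 were higher and 2178 lower of 10768. Sult1a1 (1.61 ± 0.10), a sulfotransferase, Cd74 (1.4 ± 0.10), Ltb (1.34 ± 0.08), Mettl7a1 (1.28 ± 0.08) and Ifitm1 (1.20 ± 0.08), an interferon-induced membrane protein, were higher there. Pf4 (-2.54 ± 0.12), Top2a (-2.50 ± 0.09), a topoisomerase, Nkg7 (-2.44 ± 0.09), Tyms (-2.13 ± 0.10), thymidylate synthase, and Mcm5 (-2.07 ± 0.09), a replicative helicase subunit, were lower.

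In the HSC compartment all 43 S phase genes were lower in cells rich in HSC genes (median -1.61, 43 adjusted over the list alone), with camera adjusted p = 7.0e-37 and adjusted p = 0.0473 with an estimated correlation. Of 53 G2/M genes 49 were lower (median -1.96, 51 adjusted over the list alone), of 20 strict mitotic genes 19 (median -2.50, 20 adjusted over the list alone), of 24 oxidative phosphorylation genes 22 (median -0.43, 22 adjusted over the list alone) and of 20 growth and biogenesis genes 18 (median -0.59, 18 adjusted over the list alone). All 7 megakaryocyte genes were lower (median -1.67, 7 adjusted over the list alone), with Itga2b at -2.22 ± 0.11, as were 13 of 21 platelet and megakaryocyte genes (median -0.70, 13 adjusted over the list alone) and 7 of 9 heat shock genes (median -0.24, 7 adjusted over the list alone). Higher were 15 of 17 immediate-early genes (median 0.72, 15 adjusted over the list alone), 18 of 21 interferon genes (median 0.68, 19 adjusted over the list alone), 6 of 7 MHC class II genes (median 0.71, 7 adjusted over the list alone), 5 of 7 MHC class I genes (median 0.33, 5 adjusted over the list alone), 6 of 9 quiescence genes (median 0.50, 6 adjusted over the list alone) and 59 of 99 ribosomal protein genes (median 0.11, 61 adjusted over the list alone). Among them were Klf6 (1.10 ± 0.09), Iigp1 (1.18 ± 0.12), H2-Aa (0.98 ± 0.07) and Txnip (0.96 ± 0.05). Apart from S phase, adjusted p was 0.173 to 0.249 with an estimated correlation. Mitotic cells made up 14.7%, 29.2%, 21.1% and 16.3% of the low class of compartment cells in mice 1 to 4 and 1.60%, 3.93%, 2.65% and 3.23% of the high class. Median depths were 8847, 10127, 9972 and 10071 UMIs in that low class and 7498, 6736, 7765 and 7926 in the high class. A gene with unchanged molecules per cell would therefore be higher in the shallower high class. Molecules per cell were not compared, which limits the smaller medians most.

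Over all cells the same lists were called with the same signs in cells rich in HSC genes, except platelet and megakaryocyte genes (median -0.28, adjusted p = 0.242). Other lineages were lower for 17 of 17 erythroid (median -5.14), 9 of 9 erythroblast (-5.73), 8 of 8 neutrophil (-5.87), 7 of 10 myeloid progenitor (-4.05) and 3 of 4 B cell genes (-2.85). With classes made from summed UMIs of the list, the B cell genes Cd79a (0.66, adjusted p = 0.239) and Cd79b (0.60, adjusted p = 0.0363) had the other sign. Adjusted over the list alone the counts were 17, 9, 8, 7 and 3, and adjusted p was 0.0943 to 0.271 with an estimated correlation. For the lists called on both sets of cells it was 0.161 to 0.618. Lymphoid progenitor genes (median 0.32, mean -0.19, adjusted p = 0.622, direction up), multipotent progenitor genes (median 0.17, mean -0.32, adjusted p = 0.737, direction down) and glycolysis genes (median -0.04, adjusted p = 0.528) were not called. Also not called, in the compartment, were erythroid (median -0.33, adjusted p = 0.148), erythroblast (0.43, 0.0803), myeloid progenitor (0.35, 0.131), lymphoid progenitor (0.25, 0.665), multipotent progenitor (-0.16, 0.471), neutrophil (0.20, 0.313) and glycolysis genes (-0.08, 0.282).

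Cells detecting many immediate-early genes were also high in HSC and antigen presentation genes and low in cycle genes. The HSC, MHC class I, MHC class II, S phase, G2/M and strict mitotic lists had adjusted p = 0.129 to 0.334 with an estimated correlation over all cells and 0.146 to 0.174 in the compartment. Over all cells 1216 genes were higher and 1956 lower of 11161, with 217 higher and 940 lower without the mouse block, and 382 and 1067, 166 and 800, or 569 and 1325 without mouse 1, 3 or 4. Within the HSC compartment 1929 were higher and 2004 lower of 10777. There Cd74 (1.14 ± 0.06), Ltb (1.11 ± 0.05), Irf1 (1.09 ± 0.08), an interferon regulatory factor, Procr (1.03 ± 0.07) and Nfkbia (1.01 ± 0.05), the NF-kappaB inhibitor, were higher. Top2a (-2.21 ± 0.14), Tyms (-1.97 ± 0.09) and Pf4 (-1.88 ± 0.14) were lower, each in 4 of 4 mice. Over all cells the low class included 4.70%, 37.6%, 5.74% and 2.885% erythroid-like cells in mice 1 to 4. The high class included 0.294%, 0.990%, 0.621% and 0.549%.

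Of 19 HSC genes 15 were higher and 1 lower in compartment cells rich in immediate-early genes (median 0.41, 15 and 1 adjusted over the list alone), with Mllt3 at 0.92 ± 0.05 and Ly6a at 0.92 ± 0.06. Also higher were 6 of 7 MHC class II (median 0.68, 6 adjusted over the list alone), 5 of 7 MHC class I (0.25, 5), 19 of 21 interferon (0.51, 20), 8 of 10 quiescence (0.49, 8), 53 of 100 ribosomal protein (0.07, 55) and 4 of 6 neutrophil genes (0.58, 4), with Camp at 0.81 ± 0.18, which did not pass without mouse 3 (0.33). The most abundant neutrophil gene, S100a8, was low in the compartment, at 30.7 CPM against 1441 over all kept cells. At the thinned depth it was detected in 13.4% of compartment cells. Lower were 43 of 43 S phase (median -1.45, 43 adjusted over the list alone), 50 of 53 G2/M (-1.53, 50), 19 of 20 strict mitotic (-1.97, 19), 7 of 7 megakaryocyte (-1.31, 7), 13 of 21 platelet and megakaryocyte (-0.49, 13), 6 of 13 erythroid (-0.19, 6), 22 of 24 oxidative phosphorylation (-0.33, 22), 18 of 20 growth and biogenesis (-0.44, 18) and 6 of 9 heat shock genes (-0.12, 6). All 16 lists had adjusted p = 0.146 to 0.258 with an estimated correlation. Mitotic cells made up 13.6%, 27.2%, 18.8% and 15.96% of the low class of compartment cells in mice 1 to 4 and 2.56%, 5.24%, 4.64% and 2.35% of the high class. Median depths were 8775.5, 9626, 9526 and 9724 UMIs in that low class and 7304, 6727, 8011 and 7782 in the high class. Here too a gene with unchanged molecules per cell would be higher in the shallower high class, and molecules per cell were not compared. Over all cells 16 lists were called as well, with adjusted p = 0.129 to 0.334 with an estimated correlation. There lymphoid progenitor genes were called up (1 of 6, median 0.65, 1 adjusted over the list alone) and neutrophil genes down (5 of 9, median -2.19, 5 adjusted over the list alone), against the sign within the compartment. B cell genes (median -0.36, test direction up, adjusted p = 0.721) and monocyte genes (median 0.32, adjusted p = 0.367) were not called. Nor were multipotent progenitor (0.36, 0.665), myeloid progenitor (-0.28, 0.114), platelet and megakaryocyte (-0.35, 0.134), ribosomal protein (0.01, mean -0.01, 0.340) and glycolysis genes (0.02, mean -0.02, direction down, 0.765). In the compartment the multipotent progenitor list (median 0.03, mean -0.33, adjusted p = 0.668) and the myeloid progenitor, lymphoid progenitor, erythroblast and glycolysis lists (adjusted p = 0.0634 to 0.487) were not called.

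**Figure D3:**
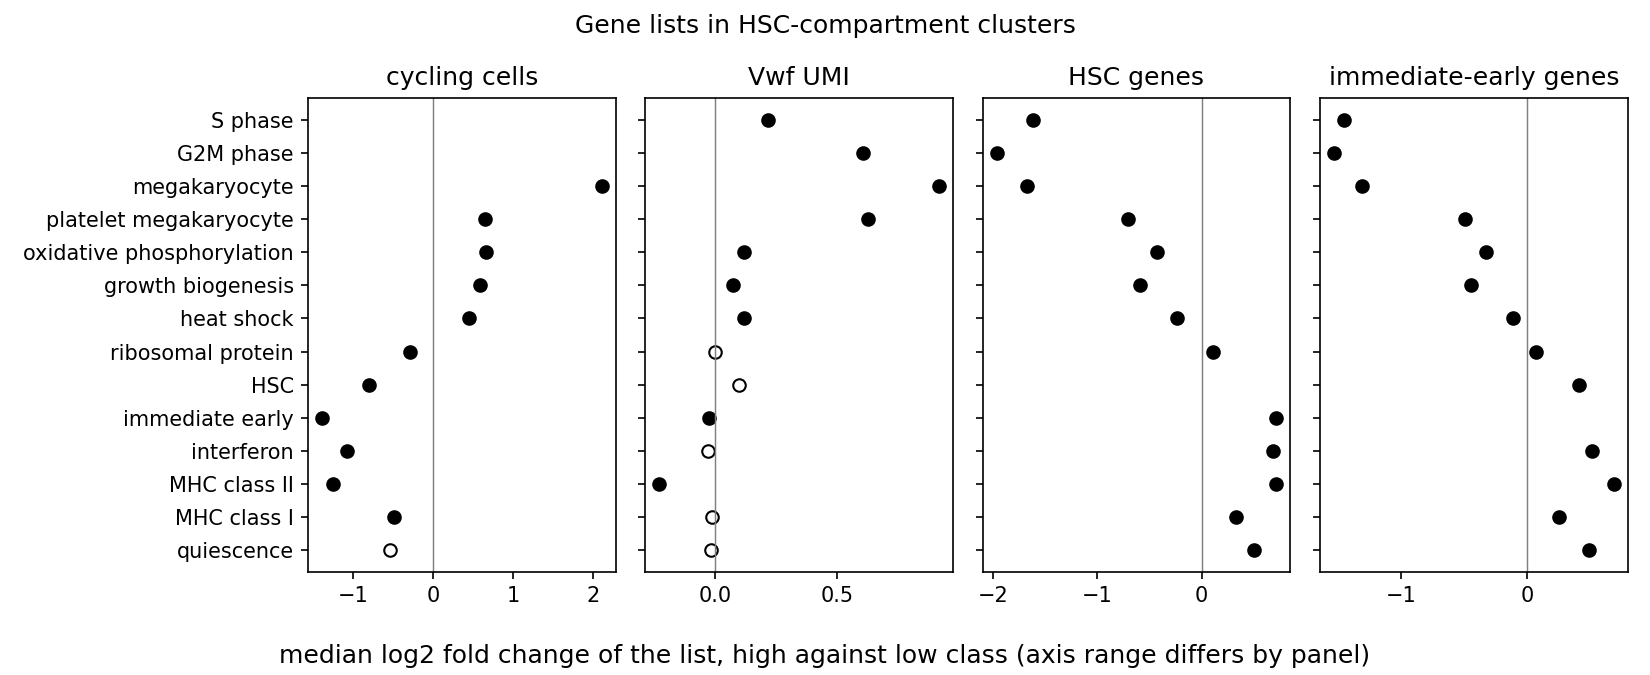
Median log2 fold change (x axis, its range differing by panel) of 14 gene lists (y axis) between the high and low class of compartment cells in the 4 comparisons, with filled points for lists past camera's threshold at the preset correlation and open points for lists that were not. With an estimated correlation only the S phase list in the cells rich in HSC genes stayed past the threshold. S and G2/M lists are absent from the first panel and the index list from its own. Replication and megakaryocyte genes lie to the left in the cells rich in HSC or immediate-early genes, and MHC class II genes to the right.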

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

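The tests of doublets and free RNA for the erythroid-like cells and the 3 tests of the Gkn3 cluster were chosen after the result was seen. Of 56 values per mouse that were screened, 8 had 1 mouse far from the other 3. For any 1 value chance gives about 1 in 20. The values share cells and totals and so depend on each other, so their count cannot be set against that rate.

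In 7 of the 8 the mouse set apart by this screen was mouse 2. Procr was at 39.6 CPM (118.6 to 127 in mice 1, 3 and 4), Robo4, a guidance receptor gene, at 3.44 CPM (8.80 to 9.33), and Tie1, a receptor kinase gene, at 18.7 CPM (42.2 to 44.5). In the HSC compartment alone these were 77.4 (132 to 141), 6.80 (9.71 to 10.4) and 36.4 CPM (47.6 to 48.7). The erythroid-like cluster held 21.6% of its cells (1.51% to 3.03%) and the HSC compartment 76.0% (91.0% to 93.4%). Cluster 3 held 49.9% of its cells (0 to 0.0713%), but without centring within mice the best match of cluster 3, shared with cluster 2, held 15.2% of mouse 2 and 8.06% to 13.8% of the others. The interferon cluster held 1 cell of mouse 2 against 5, 9 and 5 of mice 1, 3 and 4, and the exact 95% interval of its 0.081% (0.0021% to 0.450%) covers the 0.30% to 0.321% of the others. In mouse 1, 8.92% of barcodes had over 10% mitochondrial UMIs, against 0.158% to 1.16% in the other mice. The 77 barcodes under 500 genes, left out of every comparison, carried hemoglobin genes at 95.4% of their UMIs (94.99% to 95.6% per mouse), against 0.454% to 0.695% in kept cells.

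Erythroid-like cells held a larger share of mouse 2 than of the other mice. With 1 floor of 10000 UMIs for all mice they were 44.9% of mouse 2, with a lower 95% bound of 40.7%, above the highest upper bound of the others (10.99%), which argues against cell calling and depth. In mouse 2 their HSC-list CPM without Ly6a was 8.39% of that of compartment cells, whose clusters had been chosen partly by this sum. An HSC whose RNA was diluted to the median depth of the erythroid-like cells would leave 27.2%. This argues against doublets with HSCs and against free RNA in droplets with HSCs. An animal difference, or a difference in how mouse 2 was sorted, may remain, since with 1 group and 1 library per mouse no biological explanation was tested.

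The Gkn3 cluster held a larger share of mouse 3. Without centring within mice a cluster led by Gkn3 still held 17.3% of mouse 3, against centring as the source, and Gkn3 CPM in erythroid-like cells was 0.0111 of that in compartment cells (3 against 3370 UMIs, upper bound 0.0325), against free RNA. A shift of the whole library cannot be told apart from a population of cells. With clusters built without Gkn3, the share of mouse 3 cells with Gkn3 UMIs inside the best matching cluster was 1.95 times that outside (1.69 to 2.26), between the bounds set, and that cluster overlapped little with the first (shared fraction 0.175, 39.98% of mouse 3). An earlier form of the test gave 5.42 (4.79 to 6.14) but used clusters built with Gkn3, so it decided nothing, and no biological explanation was tested.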

How the results depend on the processing

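The HSC compartment, its values without mitotic cells or the Gkn3 cluster, its estimated correlations, and the clusterings without each mouse were chosen after the data were seen. Of the 70, 84, 82 and 74 genes named in the cycle, Vwf, HSC-list and immediate-early comparisons over all cells, 67, 17, 44 and 36 kept their direction and side of the threshold in every alternative run. Apart from reversals, over all cells 1, 209, 52 and 73 of the 1183, 1363, 1433 and 1314 alternatives in the cycle, Vwf, HSC-list and immediate-early comparisons ended a call and 0, 35, 3 and 3 gave one. Within the compartment no named gene reversed. The cause of the changes given here was not tested. Genes near the threshold and the 6.10% to 7.74% false calls on simulated counts limit what the smaller folds can show.

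Both classes came from the same animals, so the mouse was a block. With no replicate block the Vwf comparison called 29 genes instead of 575 and the immediate-early comparison 1157 instead of 3172, and 50 and 22 of their named genes and 3 of the HSC-list comparison no longer passed. It changed no other call of a named gene. The cycle and HSC-list comparisons called 5688 and 2717 genes without it, and the lists called were 12 instead of 13 (cycle), 13 instead of 19 (Vwf), 17 instead of 18 (HSC list) and 16 in both fits (immediate-early).

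The Vwf comparison called 279 genes with a DESeq2 test, 336 with thinned counts, 330 without mature-lineage clusters and mitotic cells, 255 with at least 2 UMIs of Vwf, and 931 in the compartment without the Gkn3 cluster. In the compartment without mitotic cells it called 302, the HSC-list comparison 2955 and the immediate-early comparison 2523. With an estimated correlation the lists called were 0 of 13 (cycle), 3 of 19 (Vwf), 0 of 18 (HSC list) and 0 of 16 (immediate-early) over all cells, and 0 of 12, 0 of 13, 1 of 14 and 0 of 16 in the compartment. Spread between mice was 14.3% with thinned counts and 11.5% in the compartment. At resolution 0.3 the best match of the Gkn3 cluster held 51.4% of cells and was also the best match of cluster 0.

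Leaving out 1 mouse gave 4427 to 6065 (cycle), 237 to 743 (Vwf), 1102 to 5206 (HSC list) and 966 to 4444 (immediate-early) genes over all cells, and 5099 to 5889, 326 to 707, 3197 to 4291 and 2786 to 3555 in the compartment. The lowest values over all cells were without mouse 3 for Vwf (237), HSC list (1102) and immediate-early (966). The HSC-list count was 1783 without mouse 1 and 2124 without mouse 4, and the immediate-early count 1449 and 1894. In the compartment 326 Vwf genes were called without mouse 3. Lists called ran from 12 to 15, 16 to 19, 17 to 19 and 15 to 18 over all cells and 12 to 13, 12 to 14, 14 to 15 and 15 to 17 in the compartment. Spread ran from 10.1% (without mouse 2) to 26.0%, clusters from 12 to 13, mitotic cells from 12.1% to 19.6%, erythroid-like cells from 2.15% (without mouse 2) to 8.88%, the HSC-list sum from 1597 to 1998.5 CPM, and the Gkn3 cluster from 6.22% to 22.4%. It was 22.4% without mouse 1 and 15.3% without mouse 3, where the matching clusters overlapped little (0.283 and 0.0505 shared).

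Reversed log2 changes were mostly those of genes of other lineages. In the cycle comparison they were Car1 -0.10, Jchain 1.21 and Slpi 2.57 in the compartment, and Jchain 1.24 and Slpi 2.51 there without the Gkn3 cluster. In the Vwf comparison they were Ngp 0.042, Cd79b 0.053, Lyz2 0.094 and Cd74 0.025 in the compartment without mitotic cells, Klf1 0.11 in the compartment, Klf1 0.27 and Hspe1 0.14 without the Gkn3 cluster, and Cdca8 at -0.17 without mature-lineage clusters and mitotic cells and -0.022 with at least 2 UMIs. In the HSC-list comparison summed UMIs gave Jchain 1.61, Mzb1 1.51, Slpi 1.71, Cd79a 0.66 and Cd79b 0.60. The compartment gave Car1 0.45, Camp 0.10, Ngp 0.33, Lcn2 0.11, Hba-a2 0.42, Hba-a1 0.60, S100a8 0.29, S100a9 0.37 and Hbb-bs 0.28. Without mitotic cells these were Car1 0.33, Ngp 0.15, Lcn2 0.077, Hba-a2 0.23, Hba-a1 0.35, S100a8 0.22, S100a9 0.36, Hbb-bs 0.092 and Jchain 0.18. Without the Gkn3 cluster they were Car1 0.40, Camp 0.0065, Ngp 0.37, Lcn2 0.20, Hba-a2 0.46, Hba-a1 0.63, S100a8 0.25, S100a9 0.32 and Hbb-bs 0.30. All cells without mature-lineage clusters and mitotic cells gave Ngp 0.16, Hba-a2 0.078, Hba-a1 0.23, S100a9 0.28 and Hbb-bs 0.037.

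In the immediate-early comparison the compartment gave Hba-a2 0.087, Hba-a1 0.14, Elane 0.11, Hbb-bs 0.12, Car1 0.34, Hbb-bt 0.26, Camp 0.81, Ngp 0.58, S100a8 0.15 and S100a9 0.27. Without mitotic cells they were Hba-a2 0.024, Hba-a1 0.11, Hbb-bs 0.12, Car1 0.17, Hbb-bt 0.13, Camp 0.77, Ngp 0.54, S100a8 0.057 and S100a9 0.25. Without the Gkn3 cluster they were Hba-a2 0.092, Hba-a1 0.16, Hbb-bs 0.10, Car1 0.27, Hbb-bt 0.27, Camp 0.81, Ngp 0.61, S100a8 0.14 and S100a9 0.23. All cells without mature-lineage clusters and mitotic cells gave Hba-a2 0.048, Hba-a1 0.21, Hbb-bs 0.16, Hbb-bt 0.13, Camp 0.73, Ngp 0.56 and S100a9 0.24.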

Other observations

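The splits of the sums, the random classes of cells and the checks of the list's remaining genes and of single mice were chosen after the result was seen, as was the HSC compartment itself. Clusters of the HSC compartment differed in their leading genes. Cluster 2 was led by Cd34 (195 CPM against 49.8 in all other cells), Sox4 (216 against 81.7), Rgs2 and Cd27, a surface protein of progenitors. It held 12.2%, 10.5% and 10.1% of mice 1, 3 and 4 and 0.243% of mouse 2, while cluster 3, with 616 of 618 cells from mouse 2, was also led by Cd34 (154 against 53.6) and Sox4, together with the MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1. Without centring within mice both had 1 best match, which held 13.8%, 15.2%, 8.45% and 8.06% of mice 1 to 4.

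The Gkn3 cluster was led, after Gkn3 (433 CPM against 27.6), by Plscr2 (101 against 21.3), Alcam (78.4 against 22.0), an adhesion molecule, Clec1a and Vwf (98.7 against 33.3). The mitotic cluster 6 was led by Top2a (777 against 93.1) and also by Pf4 (1777 against 269). The unnamed cluster 8 carried Jchain, Mzb1, Prg2, Txndc5 and Derl3, and Jchain was at 0.389%, 0.0279%, 0.164% and 0.257% of the UMIs of kept cells in mice 1 to 4. Leading genes describe the clusters they define and are not tested.

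G2/M genes were higher in Vwf-detected cells of the HSC compartment, with 42 of 53 called and a median of 0.61 (adjusted p = 0.0859 with an estimated correlation). With thinned counts 21 of 49 were called and the median was 0.53, which argues against the extra weight of deeper cells in the sums. The classes were not matched on depth. Median depths were 8709, 9780.5, 10086 and 9456 UMIs in Vwf-detected and 8090, 8084.5, 8563 and 8835 in other compartment cells. A link of Vwf detection to deeper cells was therefore not tested. Of 20 index genes detected as often as Vwf, 0 gave a median as high or higher, the highest being 0.49 for Becn1. This argues against a property of any gene detected this often. Without mitotic cells the list's median for Vwf was 0.080. Over the 24 list genes that do not define mitotic cells and were tested in both fits it went from 0.38 to 0.0029. Mitotic cells are therefore a candidate explanation. However, cells were removed by genes of the same list, which lowers its median by construction for those genes. Mitotic cells were a higher share of Vwf-detected than of other compartment cells in mice 2, 3 and 4 but not in mouse 1 (8.02% against 8.54%), where the list's median change in log2(CPM + 1) was 0.31 (0.47 to 0.67 in the others), so a higher share leaves mouse 1 open. Over all kept cells the share was lower with Vwf in mice 1 (8.51% against 10.6%) and 2 (28.3% against 33.4%), and with 1 group no biological explanation was tested.

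The 8 splits of the 8 sums that part all 4 pairs of sums from 1 mouse are too few for a share under 0.05. Of these, 1, the real one, gave as many genes in each comparison. The real values were 5947 (cycle), 575 (Vwf), 3696 (HSC list) and 3172 (immediate-early), and the highest other was 0 in each. In the other splits the difference between classes stays in the sums as spread. Low counts there were therefore largely fixed in advance and decide nothing. Of all 35 splits, 3 could not be fitted with the mouse block, and those that keep some pairs together gave at most 0, 1, 0 and 0.

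Random classes, of 50% and 25% of each mouse's cells at the thinned depth from all clusters, gave 0 to 3 calls over 10 draws. They differ in cells and in sizes from the Vwf classes of the compartment, so they are no matched control for that comparison. Within the compartment, classes made by 20 other genes detected as often as Vwf gave 0 to 497 calls, against 820 for Vwf. Art4, Bri3 and Nub1, which are in none of the lists, gave the most, with 497, 452 and 438.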
